A study of Mus musculus with 25 samples.

How the data were processed

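Total RNA of pooled mouse livers was labelled with biotin and hybridised to Affymetrix mouse whole-genome arrays, per the labels' protocols. The analysis used the table of 25 arrays and 45101 probe sets that the authors deposited with the series. Its values are intensities on a linear scale, from 12.6 to 25175, as read from the deposited table. RMA, which corrects background, normalizes and summarises the probes of a set, was applied per the submitters' processing notes; its version, the background step and the scaling are not given in the sources used here. The arrays had unequal distributions: their medians lay between 42.6 and 46.2 and their means between 140.5 and 210.4. It is therefore open whether the normalization step was applied to these values, and the main counts of genes are also given under other scalings. The tests had been planned for log2 values, so the log2 of each intensity was taken first and everything else was done on that scale. No pseudocount was needed.

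Probe sets were named from the platform's annotation. Of the 45101 sets 34958 carried 1 gene symbol, 932 carried several and 9211 had none (9160 without the controls of the array). Symbols were updated through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols and held no match for 204 probe sets. No genome build is named for the values, so no coordinates are printed. A gene was represented by the probe set with the highest mean over the 14 pools, which gave 18193 genes. Of the 9010 genes with several probe sets, 1195 had any set called between fetal and postnatal pools, and 1 had sets called in opposite directions. Sets that differed without opposite calls were not counted. Near-identical genes such as the Cyp3a, Saa, globin and Mup families can share probes, and their values are uncertain to that extent.

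Each stage is 1 pool of livers. The technical repeats of a stage, 2 arrays at 11 stages, differed by a standard deviation of 0.111 to 0.213 log2 units and were averaged before comparisons between pools. Stages of a class therefore stood in as its replicates, and their spread includes development within the class. The fetal against postnatal comparison, the slope per embryonic day over the 8 fetal pools, the slope per log2(day + 1) over the 6 later pools, and a natural spline with 3 degrees of freedom in stage order over all 14 pools were fitted to these means. The steps at birth (Day0 minus E18.5) and to adult age (adult minus Day21) were fitted to all 25 arrays with 1 mean per stage, so their errors come from technical repeats and E18.5, with 1 array, is assumed to vary like the stages with 2. All fits used limma 3.58.1 (lmFit and eBayes without trend) in R 4.3.3, with the data.table package in version 1.17.8. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes and a change of at least 1 log2 unit, taken over the whole span for the slopes and as the fitted range for the spline.

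The 33 gene lists, covering blood, liver and other cell types, cell division, hepatocyte functions, the clock, immediate early genes, sex marks and housekeeping genes, were fixed before the data were examined, and 735 of their 807 entries were measured. They came from general knowledge and not from these samples. Their shifts against other genes were tested with camera at a preset correlation of 0.01 and at a correlation estimated from the residuals. Whether the genes of a list moved on balance one way, without regard to other genes, was tested with fry. All were adjusted over the 33 lists; counts of called lists leave out the sex marks and housekeeping genes, which serve as controls. For the steps at birth and to adult age only called members were counted. The genes named in the text followed a rule fixed before the data were examined: the 6 largest called changes per direction (for fetal against postnatal also without overlap of the classes), up to 4 called members and 2 others of each list, and 12 genes in any case; 11 of these were measured. Not every gene the rule admits is printed.

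The fits were tested on simulated data of 18193 genes with 200 changed. A change counted as found at an adjusted p under 0.05 alone, without the threshold of 1 log2 unit. The changed genes were picked at random with the residual spread of each, so the shares may differ for genes that change in the real pools. In the fetal against postnatal design 70% of 2-fold and 94% of 4-fold changes were found, in the fetal course 58% and 88%, in the postnatal course 16% and 32%, at birth 70% and 100%, at the adult step 74% and 100% and in the spline 60% and 84%. The false share was 3.75% to 6.94%. Alternatives planned before the data were examined covered 3 other scalings, the choice of probe set, dim genes, the variance model, 1 repeat array per stage, a replicate term, other stage boundaries and time axes, and the omission of each pool. Alternatives chosen after seeing the data left out the stages with 1 array, genes known to differ between the sexes, and muscle and pancreas genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No column of the table was left out.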

Results

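Gene expression was measured in whole livers of C57/B6 mice at 14 stages from embryonic day 11.5 (E11.5) to 18 weeks after birth. The series title states its aim as a multi-stage analysis of gene expression during liver development. The livers of each stage were pooled before RNA extraction, with 12 livers at E11.5, 9 at E12.5 and at E13.5, 6 at E14.5 and at E15.5, and 3 at each later stage. There were 8 fetal pools (E11.5 to E18.5), 5 young pools (the day of birth, called Day0, and days 3, 7, 14 and 21) and 1 adult pool at 18 weeks. Technical repeat arrays were made for 11 stages, 2 arrays each, and the 3 stages E18.5, Day7 and Day14 had 1 array, which gave 25 arrays in all. The median log2 intensity of an array lay between 5.41 and 5.53, and repeat arrays of a stage correlated across genes at r = 0.986 to 0.996. No animal was measured on its own, so the number of pools and arrays limits the precision.

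The pools broadly followed the order of development. The first principal component of the 18193 genes held 63.2% of the variance and separated the early fetal pools (74.7 at E11.5 and 76.3 at E12.5) from those of Day14 (-76.6), Day21 (-76.8) and adult liver (-74.8). E18.5 (-22.5) lay beyond Day0 (-11.7) on this axis and close to Day3 (-24.5), and E14.5 (66.8) lay before E13.5 (58.5). Between neighbouring stages the most genes were called from Day3 to Day7 (1121), from E18.5 to Day0 (1070) and from Day7 to Day14 (1041), and the fewest from E13.5 to E14.5 (8). Each of these 3 largest steps involved a stage with 1 array, and the counts compare single pools on technical spread.

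**Figure D1:**
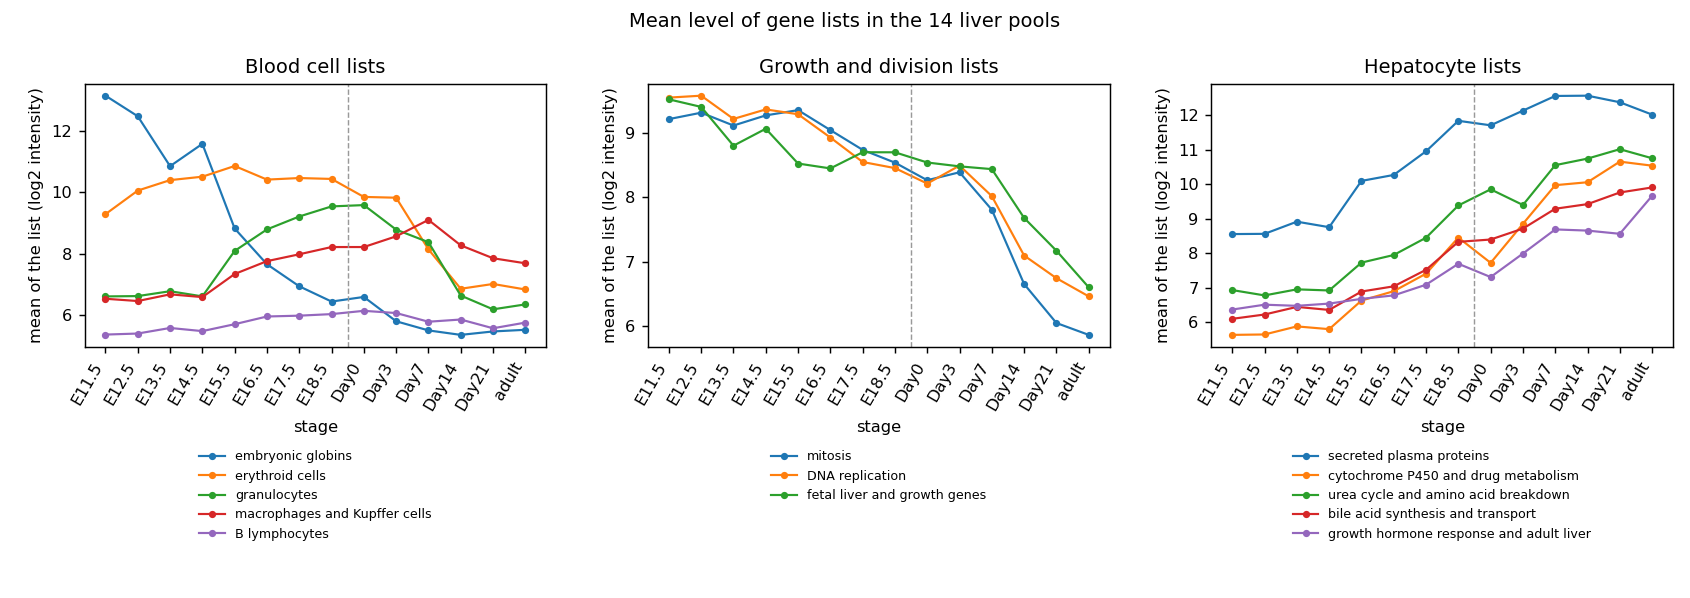
Mean log2 intensity (vertical axis) of the measured members of 13 fixed gene lists in the 14 pools, in stage order (horizontal axis), with 1 point per pool and the dashed line at birth. The embryonic globin list fell from 13.2 at E11.5 to 6.43 at E18.5, the erythroid list was highest at E15.5 (10.9), the granulocyte list at Day0 (9.59) and the macrophage list at Day7 (9.10), while the hepatocyte lists were low until E14.5.

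Fetal pools were set against the pools from birth on. Genes of red blood cell formation and of cell division were higher in the fetal pools, and genes of hepatocyte metabolism and secretion were higher after birth. Among called genes whose 2 classes of pools did not overlap, the largest excess in fetal liver was that of Scd2, a stearoyl-CoA desaturase, at 4.71 ± 0.47 log2 units (SE, 8 fetal and 6 postnatal pools), a 26.1-fold difference. The embryonic beta-like globin Hbb-bh1 (4.29 ± 0.95) and Dlk1 (3.99 ± 0.46), a membrane protein of hepatoblasts, came next, followed by Trim59 (3.74 ± 0.67), the cell-cycle regulator Rgcc (3.61 ± 0.55) and Psat1 (3.51 ± 0.64), an enzyme of serine synthesis. Among the same genes without overlap, the largest deficits were those of the drug-metabolising cytochromes Cyp3a25 (-6.93 ± 0.75, 122-fold) and Cyp3a11 (-5.57 ± 1.09). Next were Pck1 (-5.52 ± 0.44) and G6pc (-5.43 ± 0.55), which catalyse the first committed and the last step of gluconeogenesis. They were followed by Mat1a (-5.39 ± 1.06), which makes S-adenosylmethionine, and the secreted protein Fetub (-5.28 ± 0.84). Dlk1 showed no difference (-0.04) when probe sets that can match several transcripts were left out.

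In the blood lineages, 23 of 29 erythroid genes were higher in fetal pools and none was lower (26 adjusted over the list alone), among them Gata1 (2.86 ± 0.50), the master transcription factor of red cells. The ammonium transporter Rhag of red cells stood 3.95 ± 0.91 higher, but was not called (3.27) without the 3 stages that had 1 array. All 3 embryonic globins were higher (3 adjusted over the list alone), and Hba-x (3.50 ± 1.12) lost its call without any 1 of E11.5, E12.5, E13.5, E14.5, Day3, Day7, Day14, Day21 or the adult pool, with values of 2.90 to 3.46. Of 20 blood stem and progenitor genes 3 were higher (4 adjusted over the list alone), led by Lmo2 (2.72 ± 0.51), and of 16 megakaryocyte genes 3 were (5 adjusted over the list alone). None of 19 granulocyte, 17 B lymphocyte or 17 T and NK lymphocyte genes was called, over all genes or adjusted over the list alone. By contrast 4 of 20 macrophage genes were lower in fetal pools (7 adjusted over the list alone), including the Kupffer cell receptors Vsig4 (-3.39 ± 0.43) and Clec4f (-2.92 ± 0.46). Among endothelial genes 3 of 22 were lower (3 adjusted over the list alone), led by the sinusoidal lectin Clec4g (-2.97 ± 0.35). Lower levels were also found for 3 of 25 stellate and mesenchymal genes and 1 of 13 bile duct genes, with the same numbers adjusted over the list alone. The bile duct keratin Krt19 differed by -0.12 ± 0.10 (adjusted p = 0.43).

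Cell division genes were higher in fetal pools for 26 of 28 mitosis genes (26 adjusted over the list alone), such as Top2a (2.72 ± 0.68), and for 22 of 31 DNA replication genes (23 adjusted over the list alone), such as Cdc6 (3.11 ± 0.57) and the ribonucleotide reductase subunit Rrm2 (2.76 ± 0.72). The proliferation marker Mki67 was 3.04 ± 0.90 higher and lost its call without any 1 of E12.5, E13.5, E14.5, E15.5, Day14, Day21 or the adult pool (2.37 to 3.00). Of 23 fetal liver and growth genes 6 were higher and 1 lower (9 and 1 adjusted over the list alone). The imprinted regulator Plagl1 was higher by 2.45 ± 0.63, and the amino acid transporter Slc38a4, also imprinted, was lower by 5.46-fold (-2.45 ± 0.36). Some well-known liver genes were not called: albumin (Alb) differed by -0.67 ± 0.23 (adjusted p = 0.0595) and alpha-fetoprotein (Afp) by 1.27 ± 0.64 (adjusted p = 0.177), and the growth factor Igf2 by 1.15 ± 0.87 (adjusted p = 0.384).

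RNA levels of genes of hepatocyte functions were lower in fetal pools. This held for 33 of 42 genes of cytochrome P450 and drug metabolism (37 adjusted over the list alone), with the ethanol-inducible Cyp2e1 at -6.26 ± 0.92. It held for 34 of 39 genes of the urea cycle and amino acid breakdown (36 adjusted over the list alone), with the tyrosine aminotransferase Tat at -4.88 ± 0.48 and Cps1, the first enzyme of the urea cycle, at -4.61 ± 1.12. Secreted plasma proteins (22 of 29; 23 adjusted over the list alone) included Apoa5 (-5.13 ± 0.51), and the carrier of corticosteroids, Serpina6, went the other way without being called (1.87 ± 0.95). Clotting factors (18 of 21; 20 adjusted over the list alone) included F9 (-3.82 ± 0.60), and complement and acute phase genes (20 of 28; 21 adjusted over the list alone) included Mbl2 (-5.35 ± 0.80). Bile acid genes were lower for 17 of 23 (18 adjusted over the list alone), with the uptake carriers Slco1b2 (-5.55 ± 0.73) and Slc10a1 (-4.64 ± 0.93) and with Cyp7a1 (-1.76 ± 0.46), the rate-limiting enzyme of bile acid synthesis. Fatty acid oxidation genes were lower for 23 of 31 (25 adjusted over the list alone), including Cpt1a (-3.39 ± 0.36), which admits fatty acids to mitochondria. These are values of whole livers, in which the mean of the erythroid list was 10.4 at E18.5 and 6.83 in the adult pool. A smaller share of hepatocytes in the fetal pools cannot be told apart from lower levels per hepatocyte.

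Of 25 genes of glucose metabolism 12 were lower and 4 higher (13 and 5 adjusted over the list alone). The higher ones included the glucose transporter Slc2a1 (3.27 ± 0.40) and hexokinase Hk1 (2.14 ± 0.33), which serve glucose uptake and breakdown. Liver transcription factors were lower for 16 of 26 (16 adjusted over the list alone), such as the nuclear receptors Nr1i3 (-2.59 ± 0.20) and Nr1h4 (-2.50 ± 0.38), and so were 14 of 25 growth hormone and adult liver genes (15 adjusted over the list alone). Iron handling genes were lower for 8 of 17 (9 adjusted over the list alone), led by hepcidin, Hamp (-4.94 ± 0.77). Pericentral genes were lower for 7 and higher for 1 of 19 (9 and 1 adjusted over the list alone), and clock genes were lower for 4 of 16. Of 23 fat synthesis genes 6 were lower and 1 higher. The remaining lists held 1 each way of 20 cholesterol synthesis genes (3 lower and 1 higher adjusted over the list alone), 1 each way of 20 immediate early genes and 1 lower of 27 genes of other organs.

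In all, 819 genes were higher and 912 lower in fetal pools (limma, adjusted p under 0.05 and at least 2-fold), and 469 of these 1731 had no overlap between the classes. Over all 18193 genes 745 had none, a share of 4.095% against 0.0666% by chance. That chance share takes the pools as exchangeable, whereas the classes are consecutive blocks of an ordered series. A trend along the order also leaves no overlap, so the excess does not set birth apart. As groups, 23 of 31 lists differed from the other genes at the preset correlation, and none did with an estimated correlation (lowest adjusted p = 0.181 with an estimated correlation). By fry, which does not compare a list with other genes, 25 of 31 moved on balance one way. Setting the arrays to equal housekeeping levels turned the counts into 410 higher and 1673 lower, a share of 19.7% higher in place of 47.3%, with a shift of -0.45 in the median of all genes. Lines drawn at other places along the stage order called 1729 to 1912 genes, so the number alone did not set birth apart from them.

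**Figure D2:**
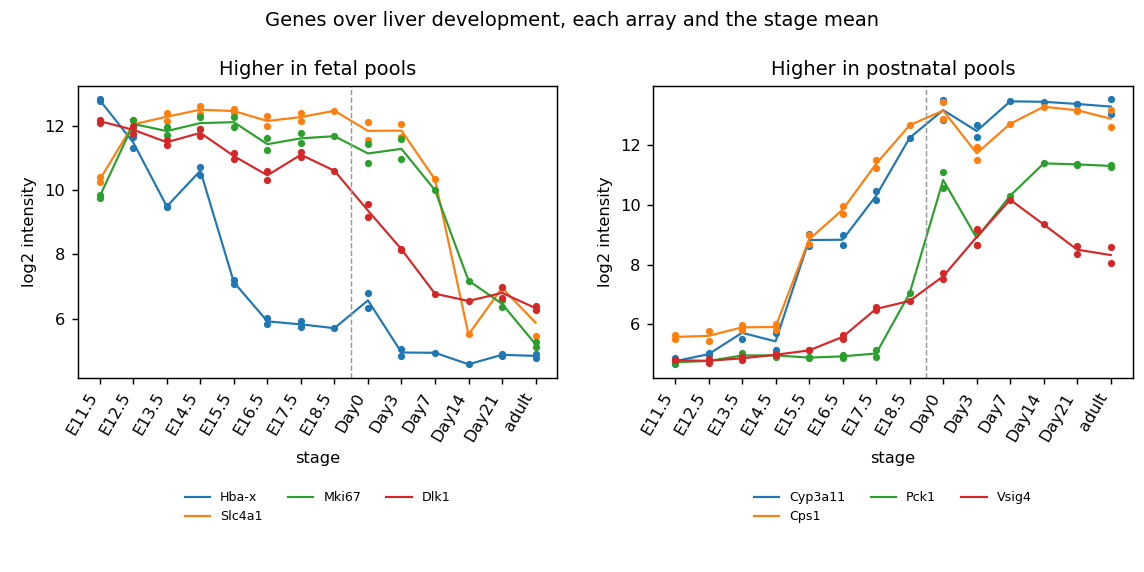
Log2 intensity (vertical axis) of 8 genes in the 14 stages (horizontal axis), with 1 point per array, the line through the stage means and the dashed line at birth. Hba-x fell in fetal life, Slc4a1 and Mki67 were lower from Day7 or Day14 on, the stage means of Cyp3a11 and Cps1 were at 8.8 or higher from E15.5 on, Pck1 was at 7.04 at E18.5 and 10.8 at Day0, and Vsig4 was highest at Day7.

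Within fetal life, a straight line over the 8 daily pools asked which genes rose or fell on balance. The changes given are fitted over the whole span and need not be steady. Cps1, for example, was at most 6.02 on the arrays up to E14.5 and at least 8.69 on those from E15.5 on. Most genes of plasma proteins, clotting factors and complement rose, and the 3 embryonic globins fell. The largest fitted rises from E11.5 to E18.5 were those of the cytochrome Cyp2d26 (8.26 ± 0.90 log2 units, SE, 8 pools, 307-fold) and of Fbp1 (8.22 ± 1.204), an enzyme of gluconeogenesis. Next came Cps1 (7.77 ± 0.91), the glutathione transferase Gsta3 (7.70 ± 0.94), Cyp3a11 (7.65 ± 0.86) and the plasma protein fetuin-A, Ahsg (7.50 ± 0.81). The largest falls were those of Hba-x (-7.69 ± 0.91, 206-fold), Hbb-y (-7.34 ± 0.71) and Hbb-bh1 (-6.79 ± 0.57). They were followed by the growth factor midkine, Mdk (-5.45 ± 0.94), the chromatin protein Hmga2 (-4.72 ± 0.66) and the tubulin Tubb2b (-4.68 ± 1.05), which was not called without E11.5 (-3.69).

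Among blood cells, 16 of 19 granulocyte genes rose and none fell (17 adjusted over the list alone), with the secondary granule proteins Lcn2 (7.15 ± 0.95), Ltf (6.60 ± 0.77) and Ngp (5.98 ± 0.75). The early granule enzyme Mpo stood at 1.25 ± 0.41 (adjusted p = 0.054) and was called without E11.5 (1.90). Macrophage genes rose for 14 of 20 (14 adjusted over the list alone), such as Lyz2 (4.34 ± 0.65), Cd5l (4.04 ± 0.55) and the scavenger receptor Marco (2.95 ± 0.32). Of 17 B lymphocyte genes 6 rose (6 adjusted over the list alone), among them the surrogate light chain Vpreb1 (2.38 ± 0.40) and the recombinase Rag1 (1.51 ± 0.25), and of 17 T and NK genes 1 rose. The stem and progenitor list went both ways: Kit (-2.89 ± 0.37) and Cd34 (-2.02 ± 0.23) were among 4 of 20 that fell (5 adjusted over the list alone), and the pan-leukocyte gene Ptprc (2.51 ± 0.27) was 1 of 2 that rose. In the erythroid list 8 of 29 rose and 2 fell, the same numbers adjusted over the list alone. Gata1 fell by 1.69 ± 0.31, and was not called at equal housekeeping levels (-0.92). As a group this list rose at the preset correlation (adjusted p = 0.00766), but not with an estimated one (adjusted p = 0.581 with an estimated correlation) or without E11.5 (median 0.07 in place of 0.72). Of 16 megakaryocyte genes 1 rose and 2 fell (1 and 3 adjusted over the list alone).

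Secreted plasma proteins rose for 24 of 29 members (26 adjusted over the list alone), with Apoh at 6.36 ± 0.61, and Alb rose by 1.59 ± 0.15. Clotting factors rose for 19 of 21 (19 adjusted over the list alone), with F11 at 6.37 ± 0.77, and complement and acute phase genes for 23 of 28 (24 adjusted over the list alone), with the pentraxin Apcs at 7.28 ± 0.88 and haptoglobin, Hp, at 7.16 ± 1.19. Rises were also found in 22 of 42 drug metabolism genes (27 adjusted over the list alone) and in 26 of 39 urea cycle and amino acid genes, with 1 fall (27 and 1 adjusted over the list alone), as for arginase, Arg1 (7.44 ± 0.91). Bile acid genes rose for 15 of 23 (15 adjusted over the list alone), with Slc10a1 at 6.14 ± 1.03 and Cyp7a1 at 2.16 ± 0.49. The counts were 16 of 31 fatty acid oxidation genes, with 1 fall (17 and 1 adjusted over the list alone), and 10 of 25 glucose genes, with 4 falls (10 and 5 adjusted over the list alone). Among lipid genes, 8 of 20 cholesterol synthesis genes rose (8 adjusted over the list alone), with Tm7sf2 at 2.40 ± 0.37, as did 7 of 23 fat synthesis genes (7 adjusted over the list alone). Nr1h4 (2.32 ± 0.34), the bile acid receptor, was 1 of 4 liver transcription factors that rose, and Gata6 (-2.45 ± 0.44) was 1 of 3 that fell. Pck1 (1.44 ± 0.59, adjusted p = 0.0991) and Cyp2e1 (4.90 ± 1.62, adjusted p = 0.0541) were not called. Cyp2e1 stood at 12.2 at E18.5, against 7.40 in the next highest fetal pool, and was called without E16.5 (5.48).

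DNA replication genes fell for 17 of 31 (17 adjusted over the list alone), such as Uhrf1 (-2.85 ± 0.33), which maintains DNA methylation, and the helicase subunit Mcm3 (-1.98 ± 0.17). Of 28 mitosis genes 6 fell and 1 rose, the same numbers adjusted over the list alone, and Mki67 was not called (0.81 ± 0.72, or -0.56 without E11.5). Fetal liver and growth genes fell for 8 of 23 and 1 rose, the same adjusted over the list alone, while Afp (0.52 ± 0.17, adjusted p = 0.0527) and Igf2 (0.46 ± 0.29) were not called. Krt19 stood at 0.07 ± 0.21, and no clock gene of 16 was called. The other lists held 7 rising of 17 iron handling genes, 5 rising of 25 growth hormone genes, 4 rising of 22 endothelial genes and 3 rising and 1 falling of 19 pericentral genes. There were also 1 rising and 2 falling of 25 stellate genes, 1 falling of 13 bile duct genes, 1 each way of 20 immediate early genes and 2 falling of 27 genes of other organs.

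In the fetal course 800 genes rose and 2179 fell (limma). With E18.5 left out, which had 1 array and high levels of several skeletal muscle genes, the counts were 728 and 2330. Of 31 lists 24 were called at the preset correlation, and none with an estimated correlation (lowest adjusted p = 0.244 with an estimated correlation). By fry 22 of 31 moved on balance one way. The balance of rises and falls rested on the scaling: at equal housekeeping levels 4924 genes rose and 564 fell, a share of 89.7% rising in place of 26.9%, with a shift of 0.80 in the median of all genes, and 6 of 17 housekeeping genes themselves fell as deposited (list median -0.92). Quantile normalisation gave 924 rises and 1434 falls.

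After birth, the 6 pools from Day0 to 18 weeks gave no gene past the threshold (limma, 0 of 18193; 2540 had an unadjusted p under 0.05). The values were nevertheless wide. The fitted change to 18 weeks was -7.05 ± 1.28 log2 units for Mki67 (SE, 6 pools; adjusted p = 0.178), -7.72 ± 1.89 for the erythroid gene Hemgn, -6.80 ± 1.46 for the granulocyte and macrophage protein Chil3, and -6.74 ± 1.11 for the imprinted gene Peg3. It was -6.45 ± 1.01 for Grb10, -5.04 ± 1.09 for Afp and -6.07 ± 2.05 for Igf2. It was 8.05 ± 1.43 for the retinal dehydrogenase Aldh1a1, 7.43 ± 1.35 for Cyp2c50, 7.20 ± 1.76 for the acute phase protein Orm1 and 6.24 ± 0.96 for the complement component C9. The values were 0.04 ± 0.28 for Alb, 0.32 ± 0.71 for Cps1 and -0.45 ± 0.17 for Krt19. Alb was the brightest gene on the Day7 and Day14 arrays (14.4 and 14.5), where a change can be understated.

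Adjusted over the list alone, 24 of 29 erythroid, 23 of 28 mitosis, 20 of 31 DNA replication, 15 of 19 granulocyte and 9 of 16 megakaryocyte genes fell. So did 7 of 23 fetal liver and growth, 4 of 20 stem and progenitor and 3 of 20 immediate early genes, while 24 of 42 drug metabolism genes, 8 of 25 growth hormone and adult liver genes, 8 of 28 complement genes and 3 of 23 bile acid genes rose. Against these, 1 drug metabolism gene, 1 growth hormone gene and 2 complement genes fell. The adult pool ends this course, and the Y-linked Eif2s3y stood at 7.21 in it and at most 5.19 in the other postnatal pools. Sex and age therefore cannot be told apart where a change rests on that pool. The growth hormone list mean was 8.56 at Day21 and 9.66 in the adult pool, and that of drug metabolism 10.7 and 10.5. No plasma protein, clotting factor, urea cycle, glucose, fatty acid oxidation or cholesterol synthesis gene passed even over its own list. As groups, 20 of 31 lists were called at the preset correlation, with the lowest adjusted p for drug metabolism (1.54e-18, higher with age) and mitosis (1.28e-17, lower), and none with an estimated correlation (lowest adjusted p = 0.268 with an estimated correlation). By fry none passed. At equal housekeeping levels, which shifted the median of all genes by 0.80, the count of 0 became 572 rises and 164 falls, and quantile normalisation gave 1 and 2. In data simulated at this design, 16% of 2-fold, 32% of 4-fold and 64% of 8-fold changes were found by the adjusted p alone.

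The step at birth compared Day0 with E18.5. Pck1 and G6pc, of gluconeogenesis, were higher at Day0, and 14 of 20 cholesterol synthesis genes were lower. The largest rises were those of the small GTPase Rab30 (4.73 ± 0.19 log2 units, 26.5-fold; SE from the technical repeats, 2 arrays against 1) and of Pdk4 (4.50 ± 0.17), the kinase that holds back pyruvate oxidation. Next came the kinase Sgk1 (4.17 ± 0.33), the uridine phosphorylase Upp2 (4.12 ± 0.29), Pck1 (3.79 ± 0.19) and the histone methyltransferase Setdb2 (3.71 ± 0.20). The largest falls were those of skeletal actin, Acta1 (-4.15 ± 0.11), of the steroid dehydrogenase Akr1c6 (-4.04 ± 0.28), and of Scd2 (-3.88 ± 0.27). They were followed by the water channel Aqp8 (-3.87 ± 0.25), the interferon-induced GTPase Iigp1 (-3.63 ± 0.26) and Ppp1r3c (-3.53 ± 0.17), which targets a phosphatase to glycogen.

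Of 20 cholesterol synthesis genes 14 fell and none rose (list median -1.77), led by Hmgcs1 (-3.21 ± 0.28), Idi1 (-3.18 ± 0.25), Sqle (-2.82 ± 0.30) and Dhcr7 (-2.71 ± 0.20). Fat synthesis genes fell for 9 of 23, with Elovl6 (-3.06 ± 0.21), fatty acid synthase, Fasn (-2.38 ± 0.18), and Scd1 (-2.25 ± 0.24). Insig2 (1.72 ± 0.26), which retains the sterol sensor in the endoplasmic reticulum, rose. Urea cycle and amino acid genes rose for 11 of 39, with Got1 (3.59 ± 0.29) and Tat (2.73 ± 0.24), and 3 fell, with Otc (-3.35 ± 0.32). Of 31 fatty acid oxidation genes 8 rose, including the thioesterase Acot1 (3.12 ± 0.27), and 5 fell, including Bdh1 (-2.70 ± 0.27) of ketone metabolism, but 5 rose and 8 fell at equal housekeeping levels. Glucose genes rose for 3 of 25, with G6pc (2.52 ± 0.30) and the coactivator Ppargc1a (2.62 ± 0.16), and 4 fell. Hamp rose by 3.64 ± 0.28 and 2 other iron genes rose with it (3 of 17). Drug metabolism genes fell for 17 of 42 and rose for 4, with Cyp3a13 at 3.03 ± 0.21. Complement and acute phase genes fell for 9 of 28. For the mean of Day0 and Day3 against the mean of E17.5 and E18.5, drug metabolism genes instead rose for 10 and fell for 4, and complement genes rose for 2 and fell for 6. The main counts were the same adjusted over the list alone. Alb, Afp, Igf2, Gata1, Mki67, Cyp2e1, Cyp7a1, Cps1 and Krt19 were not called, with values between -0.54 and 0.49, and Hba-x (0.87 ± 0.19) passed the adjusted p but not the 2-fold threshold.

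The other lists at this step held 4 falling erythroid genes of 29, with Klf1 at -1.80 ± 0.19, and 7 falling and 3 rising growth hormone genes of 25. Of 27 genes of other organs 3 fell, all of muscle. There were 4 falling and 2 rising fetal liver and growth genes of 23, 4 falling and 1 rising pericentral genes of 19, and 4 rising and 1 falling bile acid genes of 23. There were 3 falling and 1 rising clotting factors of 21, 2 rising and 1 falling plasma proteins of 29, and 2 each way of 26 liver transcription factors, with Cebpa at -2.19 ± 0.23. There were 4 rising endothelial genes of 22, 3 rising megakaryocyte genes of 16 and 2 rising granulocyte genes of 19, and at most 2 in any direction in the immediate early, clock, B lymphocyte, macrophage, stem cell, stellate, bile duct and mitosis lists. No DNA replication or T and NK gene was called. At equal housekeeping levels 9 erythroid and 15 complement genes fell, 1 bile acid gene rose and 2 fell, 1 endothelial gene rose, and 3 drug metabolism genes rose and 20 fell. With the same scaling 5 mitosis, 3 stellate and 2 DNA replication genes fell, and 1 stellate gene rose.

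The E18.5 pool stood apart in ways other than age. Several of its muscle genes were high, with Acta1 at 9.56 against at most 6.03 in the other pools, and with Myl1 (-3.18 ± 0.12) and Tnnc2 (-2.38 ± 0.12) falling to Day0. The hybridisation controls of its array averaged 10.4, against 8.31 to 9.86 in the other stages. Against E17.5, which had 2 arrays, Acta1 (-0.01), Myl1 (-0.01), Tnnc2 (-0.05), Cyp2f2 (-0.19 in place of -3.25), Igf1 (-0.71 in place of -2.87) and Saa2 (-0.32 in place of -2.51) were no longer called. Tdo2 (2.04 in place of -3.15), Saa1 (0.11 in place of -3.51) and the uncalled Cyp2e1 (4.39 in place of -0.36) had the opposite sign. Several lists also differed. Against E17.5, drug metabolism genes rose for 8 and fell for 8 of 42, complement genes rose for 3 and fell for 3 of 28, and growth hormone genes rose for 4 and fell for 3 of 25. Urea cycle and amino acid genes rose for 24 and fell for 1 of 39, fatty acid oxidation genes rose for 14 and fell for 1 of 31, and bile acid genes rose for 11 and fell for 1 of 23. Cholesterol synthesis genes fell for 12 of 20 and fat synthesis genes for 7 of 23, with 2 rises. Serpina6 fell by 3.38 ± 0.21 between E18.5 and Day0.

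At birth 660 genes rose and 410 fell (limma), and against E17.5 the counts were 475 and 229. Averaged probe sets gave 378 and 270, and the mean of Day0 and Day3 against that of E17.5 and E18.5 gave 286 and 111. The genes were only partly the same. Of the 1070 called at birth, 373 were called in the same direction against E17.5 and 280 with the means of 2 stages. Each stage is 1 pool, so these p-values measure technical spread and compare 2 pools, not the stages at large. At equal housekeeping levels 321 genes rose and 854 fell (27.3% rising in place of 61.7%; shift of -0.28 in the median of all genes), and quantile normalisation gave a share of 52.6%.

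**Figure D3:**
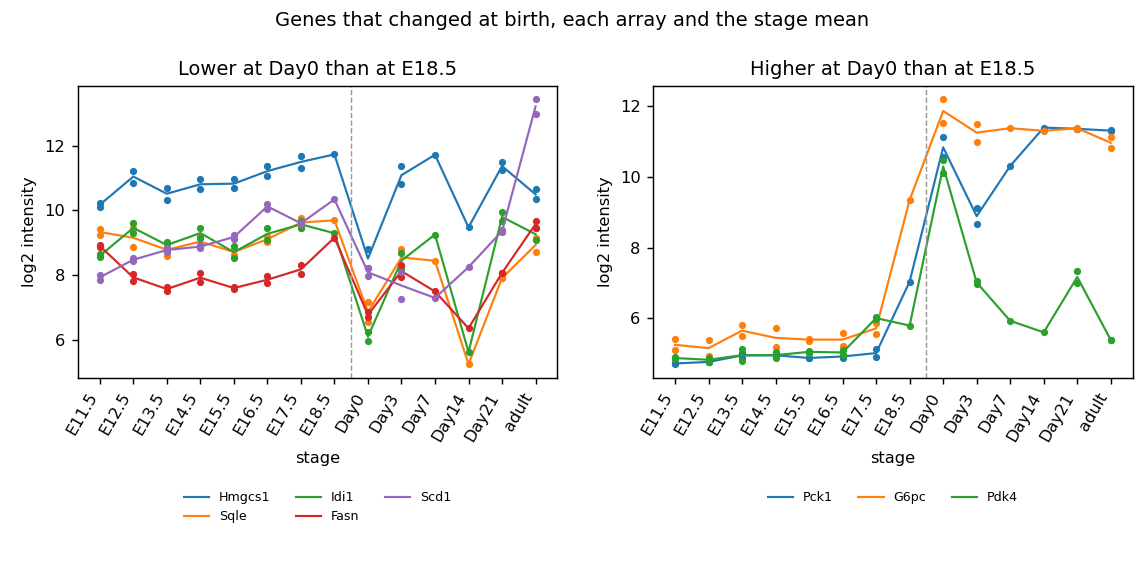
Log2 intensity (vertical axis) of 8 genes in the 14 stages (horizontal axis), with 1 point per array, the line through the stage means and the dashed line at birth. Hmgcs1, Sqle, Idi1 and Fasn were lower at Day0 and Day14 than at the stages on either side, Scd1 was highest in the adult pool, and Pck1, G6pc and Pdk4 were higher at Day0 than at E18.5.

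The last step compared the adult pool with Day21. Genes whose level is known to differ between male and female mouse liver led it in both directions. The largest rises were those of the fatty acid elongase Elovl3 (5.98 ± 0.15 log2 units, 63.2-fold; SE from the technical repeats, 2 arrays each) and of the major urinary protein Mup3 (5.97 ± 0.18). Next came Orm1 (5.26 ± 0.16), the oxysterol hydroxylase Cyp7b1 (5.09 ± 0.19), the anion carrier Slco1a1 (5.08 ± 0.17) and Cyp4a12a (5.06 ± 0.10). The largest falls were those of the sulfotransferase Sult2a2 (-7.22 ± 0.20, 149-fold), of Cyp2b9 (-5.67 ± 0.19) and of the hydroxyacid oxidase Hao2 (-5.58 ± 0.19). They were followed by the carriers Slc22a27 (-4.78 ± 0.09) and Slc22a29 (-4.62 ± 0.09) and by lipoprotein lipase, Lpl (-3.78 ± 0.20). In the same step the X-inactivation transcript Xist fell by 3.33 ± 0.18, from 10.3 to 6.93, and the Y-linked Eif2s3y rose by 3.06 ± 0.30, from 4.15 to 7.21. Kdm5d and Uty, also Y-linked, were not called.

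Of 25 growth hormone and adult liver genes 10 rose, including the steroid dehydrogenase Hsd3b5 (4.47 ± 0.13), and 4 fell. With genes known to differ between the sexes left out, chosen after seeing the data, 2 rose and 4 fell of the remaining 15. Complement and acute phase genes rose for 8 of 28, with C6 (2.95 ± 0.24) and Saa1 (2.58 ± 0.10), and 2 fell. Fat synthesis genes rose for 6 of 23, with Scd1 (3.84 ± 0.20), the malic enzyme Me1 (1.97 ± 0.11) and Fasn (1.503 ± 0.143), and none fell. Stellate and mesenchymal genes fell for 5 of 25, with collagen Col3a1 (-2.99 ± 0.19) and Sparc (-1.94 ± 0.13), and fetal liver and growth genes for 5 of 23, with Peg3 (-2.93 ± 0.24), Afp (-2.19 ± 0.19) and Grb10 (-1.96 ± 0.24). Mki67 fell by 1.26 ± 0.23. The clock gene Dbp fell by 3.12 ± 0.13 and Arntl, another clock gene, rose by 1.05 ± 0.17 (0.90, a value without a test, without replicate 2). Drug metabolism genes went both ways, 6 up and 4 down of 42, with Cyp3a16 at -3.18 ± 0.27, as did bile acid genes (3 each way of 23). Cyp4a14 (-3.07 ± 0.21) and Ppargc1a (-2.25 ± 0.13) fell. The counts were the same adjusted over the list alone. Alb, Igf2, Hba-x, Gata1, Cyp2e1, Cyp7a1, Cps1, Pck1 and Krt19 were not called, with values between -0.82 and -0.03.

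The other lists at this step held 3 falling and 1 rising erythroid genes of 29, 3 falling and 2 rising fatty acid oxidation genes of 31, and 3 falling and 2 rising clock genes of 16. There were 3 falling plasma proteins of 29, 3 falling pericentral genes of 19, 3 falling iron genes of 17 and 2 rising cholesterol synthesis genes of 20, and at most 2 in any direction in the macrophage, bile duct, urea cycle, glucose, mitosis, DNA replication, endothelial, B lymphocyte and immediate early lists. No gene of the granulocyte, megakaryocyte, stem cell, T and NK, embryonic globin, clotting factor or liver transcription factor list was called. In all 111 genes rose and 219 fell (limma). There was 1 adult pool, so the p-values measure technical spread only, and against the mean of Day14 and Day21 the counts were 191 and 170. The rising share was 33.6% as deposited, 46.1% at equal housekeeping levels (shift of 0.12 in the median of all genes) and 42.9% after quantile normalisation.

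**Figure D4:**
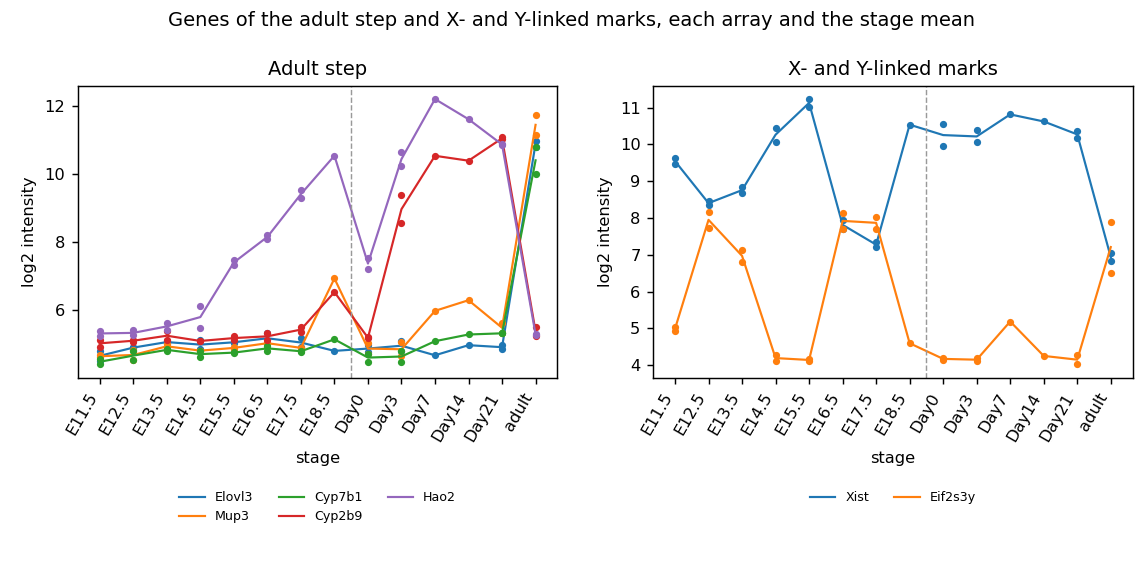
Log2 intensity (vertical axis) in the 14 stages (horizontal axis) of 5 genes that changed between Day21 and the adult pool (left) and of Xist and Eif2s3y (right), with 1 point per array, the line through the stage means and the dashed line at birth. Elovl3, Mup3 and Cyp7b1 were highest in the adult pool, Cyp2b9 and Hao2 fell there to their early fetal level, and the stage mean of Eif2s3y was 6.97 or higher in the E12.5, E13.5, E16.5, E17.5 and adult pools and at most 5.19 in the others.

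Over all 14 stages, a smooth curve fitted 5414 genes past the threshold (29.8% of those tested; limma). The widest fitted ranges were those of Tdo2 (9.62 log2 units), the first enzyme of tryptophan breakdown, which was highest in the adult pool, and of Cyp3a11 (9.31) and Fbp1 (9.07), highest at Day7. Next came Mat1a (8.96) and Cyp3a25 (8.91), highest at Day14, and Cyp2d26 (8.65), highest at Day7. Each of these fitted ranges was wider than the measured one, as for Tdo2, whose stage means lay between 4.04 and 12.6. Of the genes called, 41.7% were highest at E11.5 and 13.5% at Day7, and 1083 were lowest at Day14 and 1088 in the adult pool. Without the 3 stages that had 1 array 5320 genes were called. At equal housekeeping levels the number was 13835.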

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

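The 3 tests on sex-dependent genes, the test of the E18.5 array against E17.5 and the test on muscle genes were chosen after the result was seen. The Day14 pool for the tests on pancreas genes was chosen from 5 of these genes, whose values by stage had been seen, and the values for the 15 others were added after the result was seen.

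Among the fetal pools, E18.5 lay far from the other 7 for several hepatocyte genes, measured as the gap to the nearest pool divided by the range of the group. The gaps were 0.969 for Tdo2 (9.23 at E18.5), 0.873 for Pck1, 0.869 for Cyp3a25 (9.71, next 4.89), 0.866 for G6pc, 0.856 for Apoa5, 0.84 for Tat, 0.697 for Cyp2e1, 0.645 for Slco1b2, 0.633 for Cpt1a and 0.532 for Cyp7a1, all higher at E18.5. Serpina6 was lower there (0.652; 9.88, next 11.5). The list means of other organs (0.879), pericentral genes (0.614) and fat synthesis (0.559) were higher at E18.5. E11.5 was the lowest fetal pool for Slc4a1 (0.791), Mki67 (0.703) and Rhag (0.535), and E15.5 the highest for Lmo2 (0.595).

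Among the pools after birth, Day0 was the highest for Hba-x (0.816), the embryonic globin list (0.641) and Slc2a1 (0.699), and the lowest for Slco1b2 (0.755), Cyp2e1 (0.695) and Mbl2 (0.626). Day3 was the lowest for Cyp3a11 (0.705) and Cps1 (0.633) and the highest for the T and NK list (0.747), and Day7 was the lowest for Hamp (0.697; 8.44, next 11.6). These were 28 gaps in 178 groups of pools, where chance gives about 1 in 20, or 8.9, and 14 of the 28 were at E18.5. That share takes the pools as exchangeable, whereas E11.5, E18.5 and Day0 are the ends of groups ordered in time, and most of these genes were named for their change along that order. Of the 10092 probe sets with no gene symbol or several, which entered no comparison, 79 were higher and 107 lower in fetal than in postnatal pools.

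Of the 4 measured X- and Y-linked marks, Xist fell and Eif2s3y rose in the adult step. Kdm5d and Uty, both Y-linked, were not called, and the median of the 4 was 0.343. Of 45 listed genes known to differ between male and female mouse liver 36 were measured, 25 were called and 11 were not, and all 25 went the way of a male adult pool, and so did the 10 of 10 that the report does not otherwise name, consistent with an adult pool that held males and a Day21 pool that did not. Maturation between 21 days and 18 weeks cannot be told apart from sex, since the series has 1 adult pool. Whether a sex difference was present before adult life also stays open: the mean of the male-type genes differed by 0.068 between E17.5 and E15.5, but 12 of 17 lay below the median of all values there, and Eif2s3y was at most 5.19 from Day0 to Day21. Without the 36 measured genes of this list the step held 97 rises and 207 falls. The list need not hold every gene that differs between the sexes, so these counts are not free of sex.

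Cholesterol synthesis genes fell at birth, from an E18.5 pool with 1 array, muscle genes and bright hybridisation controls. Against E17.5 the list median was -1.293 (12 of 20 called), which argues against the E18.5 array as the whole cause. The muscle genes differed by a median of 0.017 between E17.5 and Day0, which argues against muscle in that contrast, and over 3 scalings the smallest fall in the list was -1.822. A fall at birth in these livers is a candidate explanation and remains a hypothesis, since each stage is 1 pool. A fall was not particular to birth, since the list median for Day14 minus Day7 was -1.332. Feeding and the hour of collection were not tested.

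Pancreas genes were higher at Day14 than in the other pools, with Cela2a at 8.06 at Day14, 6.46 at Day0, 6.35 at Day7 and at most 5.88 elsewhere, and Ctrb1 at 7.65, 7.49 and 7.17 in these pools. Of 20 measured pancreas genes 16 were highest at Day14, and 11 of the 15 not seen before, as pancreas taken with the livers would give. Some of these leads were small, as for Ctrc (4.90 at Day14, 4.87 at Day7) and Gp2 (5.04 and 4.92). The share of all genes highest at Day14 was not set beside these counts. A shift of all dim genes on that array is argued against by the median of 13024 genes of like level, whose Day14 excess was 0.026, against 1.138 for the 20 pancreas genes and 0.633 for the 15. Among the genes of like level the median pancreas gene lay at percentile 97.33, past the bound set in advance, but at 93.11 for the 15, short of it. No biological explanation was tested.

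In 3 tests, shuffled pools did not give the counts of genes. Neighbouring pools are alike, so groups or orders along time call more genes than shuffled ones. With 1 pool per stage, these tests cannot exclude differences between single pools, and they do not single out birth. In 100 splits of the 14 pools into 8 and 6, the real one included, 1 gave as many genes as fetal against postnatal (1731; highest other 0). In 100 orders of the 14 pools 1 gave as many as the course over all stages (5414; highest other 2), and in 100 orders of the fetal pools 1 gave as many as the fetal course (2979; highest other 0). Drawn along the stage order at 6 other places, the line gave 1729 to 1912 genes, which points to a graded order of the pools.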

How the results depend on the processing

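Alternatives that left out the stages with 1 array, the sex-dependent genes, or the muscle and pancreas genes were chosen after seeing the data; all others were planned. Of 4173 values of named genes under alternatives 3902 were kept, 88 lost and 71 gained a call, 43 reversed and 69 moved. Kept meant the same direction and side of the threshold. The steps at birth and to adult age without 1 replicate had no test. There a value of the same sign was kept within the gene's spread between repeats, and otherwise had moved. Genes of the postnatal course were uncalled to begin with. Of 969 list medians 934 kept direction and call, 34 lost the call and 1 reversed. Where no cause is given below, the cause was not tested.

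At equal housekeeping levels the counts were 410 higher and 1673 lower in fetal pools, 4924 rising and 564 falling in the fetal course, 572 and 164 in the postnatal course, 321 and 854 at birth, and 13835 over 14 stages. Quantile normalisation gave 1434 falls in the fetal course and 1 rise and 2 falls after birth. Averaged probe sets gave 1446 falls in the fetal course, 378 rises and 270 falls at birth and 145 falls in the adult. The first 4 against the last 4 fetal pools gave 392 rises and 633 falls, and stage order in place of log2 time 7 and 29 after birth. At birth, Day0 against E17.5 gave 229 falls, and the mean of Day0 and Day3 against that of E17.5 and E18.5 gave 286 rises and 111 falls. Adult against the mean of Day14 and Day21 gave 191 rises. With the correlation estimated, 0 lists were called by camera in the fetal against postnatal comparison, 0 in the fetal course and 0 in the postnatal course.

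With a replicate block (the replicate number as a term, the pool as a random block) the postnatal course held 237 rises and 694 falls, against 0 and 0 without replicate 1 or without replicate 2 (consensus correlation 0.379), and no other count of genes moved by over 1.5 times. The difference between repeats correlated above 0.1 in 38 of 55 pairs of stages (median 0.398, from -0.573 to 0.73), so the numbers were not taken as pairs. They did share a difference: among the brightest genes replicate 1 was above replicate 2 at 10 of 11 stages, by 0.011 to 0.413, with -0.285 in the adult pool. Leaving out each pool gave 590 to 1025 genes higher and 788 to 1014 lower in fetal pools, 665 to 962 rises and 1856 to 2330 falls in the fetal course and 4488 to 5559 genes over 14 stages. Counts without 1 replicate were not run for the steps at birth and to adult age, which leave no residual degrees of freedom.

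Reversed values were mostly near 0. Fetal against postnatal: Dlk1 -0.042 without _x_at and _s_at probe sets, Foxm1 -0.045 at equal housekeeping levels. Fetal course: Igf2 -0.095 with averaged probe sets, Mki67 -0.563 without E11.5 (1.247 without E12.5), Krt19 -0.032 without replicate 2 and -0.21 without E18.5 (0.354 without E11.5). Postnatal course: Alb 0 after quantile normalisation, -0.422 without replicate 2 (0.504 without replicate 1), -0.223 without Day0, -0.019 without Day3 and -0.004 without Day14; Cps1 -0.24 without replicate 2 and -0.155 without Day3 (1.3 without Day0); Krt19 0.309 at equal housekeeping levels; the median of stellate cells and mesenchyme 0.051 without the adult pool (-1.149 without Day0). Birth, against E17.5: Tdo2 2.038, Saa1 0.112, Alb 0.047, Igf2 0.133, Cyp2e1 4.393, Cyp7a1 1.225, Krt19 0.281. Birth, averaged probe sets: Igf2 0.43, Cyp7a1 0.113. Birth, means of 2 stages: Igf2 0.087, Hba-x -0.005, Cyp2e1 2.522, Krt19 0.128. Birth, without replicate 2: Gata1 0.061 (-0.259 without replicate 1, 0.001 with the replicate block), Cyp2e1 0.015 (-0.726 without replicate 1). Adult step, equal housekeeping levels: Alb 0.068, Hba-x 0.068, Pck1 0.05, Krt19 0.066. Adult step, quantile normalisation: Alb 0, Cyp2e1 0.048, Pck1 0.129. Adult step, without replicate 1 (without replicate 2): Alb 0.21 (-0.277), Cyp2e1 0.199 (-0.409), Cps1 0.02 (-0.584), Krt19 0.072 (-0.143). Adult against the mean of Day14 and Day21: Hba-x 0.114, Gata1 0.186.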

Other observations

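The relation between hybridisation controls and repeat arrays was chosen after the result was seen. The list means of blood lineages were highest at different stages. Embryonic globins were highest at E11.5 (13.2 log2 units), erythroid genes at E15.5 (10.9), granulocyte genes (9.59) and B lymphocyte genes (6.13) at Day0, T and NK genes at Day3 (6.02), and macrophage genes at Day7 (9.10). Granulocyte genes stood at 6.60 at E14.5 and 8.09 at E15.5, and were back at 6.63 by Day14. Megakaryocyte genes stood at 7.77 at both E11.5 and Day0, and stem and progenitor genes were highest at E11.5 (7.14). Endothelial (7.25) and stellate genes (8.40) were also highest at Day7. Mitosis genes were highest at E15.5 (9.36) and stood at 7.81 at Day7 and 6.65 at Day14. These are values of 1 pool per stage, without a test.

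Cholesterol synthesis genes moved up and down from stage to stage, with list means of 9.19 at E18.5, 7.48 at Day0, 8.24 at Day3, 8.81 at Day7, 7.36 at Day14 and 8.97 at Day21. Clock genes were highest at Day21 (7.01), immediate early genes at Day0 (6.63) and iron handling genes at Day21 (9.29). Secreted plasma proteins were highest at Day14 (12.6), clotting factors at Day7 (11.8), drug metabolism genes at Day21 (10.7) and complement genes in the adult pool (10.4). Between Day7 and Day14 211 genes rose and 830 fell, and between Day14 and Day21 552 rose and 96 fell. Day7 and Day14 had 1 array each, so these calls rest on the technical spread of other stages.

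Over the 11 stages with 2 arrays, the difference between repeats in the hybridisation controls went with that in the brightest genes (r = 0.81, permutation p = 0.0015; rank correlation 0.873, permutation p = 0.00098; r = 0.865 without the 2 farthest stages). Skeletal muscle genes were highest at E18.5 for 13 of 25, and for 9 of the 21 outside the list of other organs. Tnnc1 went the other way, with 9.49 at E17.5 and 6.69 at E18.5.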
